A study of Drosophila melanogaster with 4 samples.

How the data were processed

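RNA was measured in whole Drosophila melanogaster embryos of strain w118, collected 0–1 h or 4–5 h after egg laying, with 2 replicates per stage and 4 libraries in all. Per the labels' protocols, bleach-dechorionated embryos were homogenised and the lysate was cleared by centrifugation before RNA was extracted with TRI-reagent. Libraries followed the Nanopore direct RNA protocol, in which native RNA molecules are read without copying to DNA or amplification. Total RNA was used, as poly(A) tail lengths change at this time of development. The submitters' processing notes name minimap2 and Salmon and the genome build BDGP6. Their versions and settings, and any filters, are not given in the sources used here. The labels do not say whether the replicates of a stage came from separate embryo collections, so the p-values measure only the spread between these samples, which may be technical.

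The deposited tables hold 1 line per annotated transcript and library. The authors' read numbers are expected counts from Salmon, not normalised, which here were summed per gene and rounded to whole numbers. The deposited TPM were made by the authors by dividing by an effective length, which was 250 nt below the transcript length for 99.0% of transcripts. TPM served in 1 alternative only. Each table lists 30652 transcripts, of which 30280 were matched by identifier to the Ensembl release 115 annotation of BDGP6.54, a later patch than the authors may have used. The lengths of 99.4% of the matched transcripts were the same in both. The other 372 transcripts have no match and were kept under their own identifiers, and the matched ones belong to 14001 genes.

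Genes were tested with edgeR 4.0.16 in R 4.3.3 (filterByExpr at its minimum count of 10, TMM normalisation, robust quasi-likelihood fit and F test, stage as the only term). Benjamini-Hochberg adjusted p under 0.05 is the threshold throughout. An adjusted p of a single gene comes from this fit unless another fit is named or isoform usage is described. Levels are CPM (reads of a gene per 1e6 reads of the library) on TMM-scaled library sizes, given as mean ± SD with n = 2 per stage, and SE is the standard error of the fitted log2 change. Where a stage had 0 reads in both libraries the fold is a lower bound against a floor of 3 counts per library, which is 3.45, 3.66, 5.51 and 9.99 CPM in 0–1 h replicates 1 and 2 and 4–5 h replicates 1 and 2. Where a stage had 1 to 3 reads in all, the reads are given, alone or with the ratio and its 95% counting interval. Such intervals and floors cover counting error only.

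Gene lists were tested with camera in limma 3.58.1, which asks whether a list moved relative to the other genes, on log2 CPM with a prior count of 2 and the inter-gene correlation preset at 0.01. Lists with at least 5 tested members were tested, 26 in all, with adjustment over the lists. The test was repeated with a correlation estimated per list, and with fry, which asks whether a list's genes moved on balance in 1 direction. The lists were germ plasm, maternal axis, egg activation, mRNA repression and decay, genome activation, early zygotic, gap, pair-rule, segment polarity, Hox, mesoderm, dorsal ectoderm, neuroectoderm, neuroblast, Enhancer of split and Bearded, endoderm and organ primordia, cytosolic and mitochondrial ribosomal proteins, mitochondrially encoded genes, nuclear oxidative phosphorylation, proteasome, histones, replication, heat shock, splicing and cell adhesion. Lists for hemocytes, maternal somatic tissue, late muscle and cuticle, and sperm and testis held too few tested members, and only their reads and calls are given. Some genes stand in more than 1 list.

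Isoform usage was tested with diffSpliceDGE in edgeR on transcript counts, for genes with at least 2 transcripts past the filter, with the gene-level F test. In a second test, chosen after seeing the data, transcripts of a gene whose annotated 3′ ends lie within 50 nt were summed. The read-weighted mean annotated length or 3′ end was then compared between stages with a two-sided exact binomial test over genes, which are not independent replicates. Single libraries were compared in the same way. Positions of 3′ ends are chromosome coordinates, so distances between them in nt can include introns. For the level of downstream forms, genes were chosen by a gain of at least 10% in share in 1 pair of libraries and measured in the other pair. Intronless genes are those whose annotated transcripts all have 1 exon, and short genes have a span under 2000 bp.

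The genes named are the 10 largest rises and the 10 largest falls among called genes with a mean of at least 20 reads at the higher stage and the same direction in both pairs of libraries, the 3 members of each list with the smallest p, the 8 genes with the smallest adjusted p for isoform usage and any gene of a preset isoform list past the threshold, the 5 most abundant genes per stage, and up to 5 genes per direction detected at 1 stage. Genes named outside this rule were chosen after their values were seen, to describe how members of a list divided. The stage comparison, tests, lists, rule for names and most alternatives were fixed before the data were examined.

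The steps were tested on simulated data with the mean counts, depth and spread of these libraries. Both stages were drawn from the same mean profile, and few genes were changed, upward and downward alike. No shift in makeup as large as that between the real stages was simulated, so the rates do not test the scaling. Of genes given a 2-fold change, 35 of 62 were recovered (56.5%), against 64 of 66 at 4-fold (97.0%) and 59 of 59 at 8-fold, and 10 of 5605 unchanged genes were called. In the usage test, exchanges between isoforms that differed at least 3-fold were recovered in 6 of 41 genes at the measured spread and in 54 of 54 at a dispersion of 0.05, with 2 of 354 and 5 of 504 unchanged genes called. A simulated list of 30 risen genes gave p = 1.6e-109 with camera, 0.00465 with an estimated correlation and 9.8e-04 with fry, and a list of 30 unchanged genes gave 0.654, 0.662 and 0.0915.

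Alternatives were DESeq2 1.42.0, edgeR with RLE factors or with library size only, no count filter or a stricter one of 20 reads, a replicate block, thinning to the smallest library, limma on log2(TPM + 1), the robust option off, mitochondrial and rRNA genes left out, each library left out in turn, and other definitions of usage, intronless, short and stage-specific genes. Each fit with a library left out reran the count filter, so its tested genes differ as well. Further ones were added after the data were seen and are named with the sensitivity results. Reads themselves, poly(A) tail lengths, unspliced RNA and retained introns are not analysed here, since the tables hold only annotated transcripts. Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9 were used for joining tables and drawing.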

Results

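The data compare messenger RNA in fly embryos early in development: 2 libraries of embryos at 0–1 h after egg laying, when most RNA is that loaded by the mother, and 2 at 4–5 h, when the embryo's own genes are transcribed. The assay was Nanopore direct RNA sequencing, with reads assigned to annotated transcripts. The 0–1 h libraries held 573843 and 557424 reads and the 4–5 h libraries 883138 and 429534. Reads fell on 6967, 6930, 7829 and 7456 genes in the same order, and on 6873, 6847, 7261 and 7456 genes with all libraries thinned to the smallest. Cytosolic ribosomal protein genes took 23.3% and 26.2% of reads at 0–1 h and 50.2% and 49.8% at 4–5 h, and the 10 most abundant genes 5.92%, 5.56%, 11.2% and 10.1%. Reads on ribosomal RNA genes and pseudogenes were 2.20%, 0.736%, 5.33% and 3.21% of each library. The read-weighted mean transcript length was 1798, 1665, 1266 and 1338 nt, and without ribosomal protein and rRNA genes 2110.5, 1999, 1728 and 1877 nt.

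The comparison of the stages asks which transcripts were lost and which appeared across genome activation. The most abundant mRNA at 0–1 h, deadhead (dhd, FBgn0011761, chromosome X 5312171–5313125), a thioredoxin of the egg, fell from 6000 ± 30.5 to 117 ± 5.57 CPM (counts scaled to library size, mean ± SD, n = 2 per stage), a log2 change of −5.67 (SE 0.25, adjusted p = 1.2e-35). Transcripts of exuperantia (exu), which localises bicoid mRNA, fell 50.3-fold, and those of nanos, the posterior determinant, fell 42.2-fold. In the other direction Tom, an inhibitor of Notch signalling of the Bearded family, rose from 19.0 ± 4.15 to 1949 ± 65.7 CPM (log2 change 6.67, SE 0.29, adjusted p = 1.0e-35). Its relative BobA (chromosome 3L 14945499–14946125) had 0 reads in both 0–1 h libraries and 993 and 626 at 4–5 h, at least 549.9-fold higher, although closely related copies make it uncertain which copy the reads came from. Among the most abundant mRNAs at 4–5 h, RpL41, a ribosomal protein gene, rose from 2840 ± 42.6 to 17494 ± 207 CPM. The elongation factor gene eEF1alpha1 rose from 5691 ± 618 to 20321 ± 1812 CPM, although its change was −0.14 in log2 TPM.

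Of 6042 tested genes 3633 changed (60.1%), 1730 of them higher and 1903 lower at 4–5 h, and 565 rose and 885 fell at least 4-fold (edgeR). With library size only, 656 genes were called as genes higher at 4-5 h and 3823 as genes lower at 4-5 h, and DESeq2 called 1300 and 1124. The median log2 change of all tested genes was −0.10 with TMM and −1.29 with library size only, so directions here are relative to the bulk of genes and not per embryo. Replicates correlated across genes at 0.954 (0–1 h) and 0.929 (4–5 h) in log2 CPM, against 0.478 to 0.503 between stages, where genes are not independent replicates. Library makeup was not tested. Poly(A) tail lengths, on which capture may depend, were not measured, so rises and falls in reads may include changes of capture.

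Germ plasm and pole cell mRNAs, which specify the future germ line, fell as a group: 11 of 13 tested genes fell and 1 rose (over all genes and adjusted over the list alone), with a median log2 change of −3.35 (camera adjusted p = 3.1e-05). The adjusted p was 0.268 with an estimated correlation, and with library size only 13 of 13 fell. Beside exu and nanos, pgc, a repressor of transcription in pole cells, fell 20.5-fold from 899 ± 58.8 to 43.7 ± 0.526 CPM, and osk, the organiser of the germ plasm, fell by 5.78 on the log2 scale (SE 0.37). CycB, the mitotic cyclin, rose by 0.59 (SE 0.21), and aub, a piRNA pathway gene, did not pass at −0.89 (SE 0.51). Of 15 maternal axis determinants 7 fell (6 adjusted over the list alone) and 1 rose, with a median of −0.99 (adjusted p = 0.0192, adjusted p = 0.268 with an estimated correlation and 0.0737 with limma on TPM). With library size only 14 of 15 fell, with DESeq2 4 fell and 1 rose, and without 0–1 h replicate 1 edgeR called 4 lower. Those that fell included swa, which fell 13.8-fold, and the dorsal gene dl, with 73 and 42 reads against 2 and 0, a ratio of 28.8 (95% counting interval 7.78–240.2). The gene that rose was stau, an RNA-binding protein gene (log2 change 1.48, SE 0.29). The anterior determinant bcd had a log2 change of −0.99 (SE 0.53) and was not called at 20, 20, 7 and 3 reads.

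Among 21 genes of egg activation and the syncytial cell cycle 12 fell and 6 rose, the same counts adjusted over the list alone, with a median of −0.70 that did not pass as a group (adjusted p = 0.135, and adjusted p = 0.314 with an estimated correlation). It passed with no filter (adjusted p = 0.0303) and by fry (adjusted p = 0.00145), and with library size only 17 fell and 2 rose. Without 0–1 h replicate 2 edgeR called 3 higher. Among those that fell, mtrm, a Polo inhibitor, fell 44.2-fold, gnu, a PNG kinase activator, fell 21.9-fold, and fs(1)Ya, a nuclear envelope gene, fell from 248 and 220 reads to 1 in each library (ratio 117, interval 32.2–969). CycB3, a mitotic cyclin, rose from 72.8 ± 1.11 to 575 ± 12.3 CPM and fzy, which activates the anaphase-promoting complex, from 49.7 ± 0.424 to 400.0 ± 75.1 CPM. The mRNA repression and decay factors had 9 of 18 members lower and 4 higher, the same adjusted over the list alone, with a median of −0.53 (adjusted p = 0.175, and adjusted p = 0.688 with an estimated correlation), and passed with library size only (adjusted p = 0.0453), where 15 of 18 fell, at a median of −1.72, and those that rose with TMM did not. DESeq2 called 2 higher and 5 lower. Without 0–1 h replicate 1 or 4–5 h replicate 1 edgeR called 5 lower, and without 0–1 h replicate 2 or 4–5 h replicate 2 it called 1 higher. Within that list wisp, a cytoplasmic poly(A) polymerase, fell 6.86-fold, tral fell 4.19-fold and me31B, an RNA helicase of repressed mRNPs, fell 3.63-fold. Heat shock and chaperone genes fell in 9 of 11 cases and rose in 2, also adjusted over the list alone, with a median of −2.71 (adjusted p = 0.00563, and adjusted p = 0.268 with an estimated correlation). With library size only 9 of 11 fell and the 2 that rose were not called, and DESeq2 called 6 lower and 2 higher. Hsp26 fell 34.9-fold from 1801 ± 27.8 CPM, Hsp27 fell 22.9-fold and Hsp83 fell 10.2-fold, while Hsp23 rose by 1.84 (SE 0.31).

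Tested genes that lay out the body plan were higher at 4–5 h, list after list, with TMM, RLE, DESeq2 and library-size scaling alike. A gene with few reads at 0–1 h passes the count filter only through its reads at 4–5 h. For such members being tested nearly set the rise, so the shares below do not stand for whole lists. Tested were 10 of 14 gap, 8 of 13 pair-rule, 9 of 18 segment polarity and 5 of 12 Hox genes. Over all genes 1730 of 6042 tested rose. Gap genes, the first zygotic tier of the anterior-posterior axis, rose in 8 of 10 cases: D rose from 4.77 ± 1.88 to 189 ± 38.9 CPM, and Kr, the central gap gene, from 5.38 ± 2.74 to 112 ± 2.22 CPM. The 2 that fell, cad (log2 change −3.20, SE 0.34) and hb (−0.92, SE 0.31), are also supplied by the mother, and DESeq2 called 1 gap gene lower. Of the 8 tested genes listed as pair-rule 6 rose, while ftz-f1 fell, as did Tl, a maternally supplied receptor of the dorsal-ventral axis that the preset list held by mistake. Without Tl, an alternative added after the data were seen, 6 of 7 rose, with a median of 3.79 (camera adjusted p = 0.00528, and adjusted p = 0.255 with an estimated correlation). Risers included slp1 (0 and 2 reads against 64 and 42, ratio 106, interval 28.6–887) and drm (65.4-fold). Of 9 segment polarity genes 6 rose and 1, smo, fell, which DESeq2 did not call, while 2 fell with library size only. The selector gene en had no reads at 0–1 h and was at least 21.5-fold higher, gsb at least 33.0-fold higher, and the beta-catenin gene arm rose 7.30-fold. All 5 tested Hox and cofactor genes rose, among them hth (2 and 0 reads against 97 and 82), tsh (at least 32.6-fold higher) and Abd-B (at least 9.29-fold higher). In that list 8 rose when either 0–1 h replicate was left out. The median log2 changes of these 4 lists were 5.16, 3.48, 5.70 and 7.33, or 4.80, 3.48, 3.06 and 4.32 with genes unseen at 0–1 h at their bound, and the counts were the same adjusted over each list alone. Their camera adjusted p were 0.00418, 0.0211, 0.00418 and 0.00132. With an estimated correlation the adjusted p were 0.268, 0.314, 0.275 and 0.268. Thinning to the smallest library also ended the gap and pair-rule calls (adjusted p = 0.0632 and 0.0568), as did the stricter filter for pair-rule genes (adjusted p = 0.239). Without Tl the pair-rule list passed with thinning (adjusted p = 0.0179) and had too few members under the stricter filter.

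Tissue-forming genes showed the same direction, with the same limit from the count filter. Tested were 10 of 21 mesoderm, 10 of 21 dorsal ectoderm, 6 of 17 neuroectoderm and 13 of 21 neuroblast genes. In the Enhancer of split and Bearded list 14 of 17 were tested, and of endoderm and organ primordia genes 8 of 20. Mesoderm genes rose in 7 of 10 cases and 1 fell (6 and 3 with library size only, and the 1 was not called by DESeq2), with Ilp4, an insulin-like peptide gene, rising from 3.01 ± 2.64 to 355 ± 134 CPM and the heart gene tin at least 27.5-fold higher. In the dorsal ectoderm list 8 of 10 rose (2 fell with library size only), including Doc1 (0 and 1 reads against 44 and 24, ratio 136, interval 23.6–5450) and the GATA factor pnr (at least 20.6-fold higher). All 6 tested neuroectoderm genes and 12 of 13 neuroblast genes rose (11 rose and 1 fell with library size only). Examples are l(1)sc, a proneural gene (0 and 1 reads against 90 and 41, ratio 262, interval 46.2–10426), SoxN, a neural Sox factor (at least 34.2-fold higher), and mira, which sorts neuroblast determinants (5.96 ± 1.93 to 244 ± 43.9 CPM). All 14 tested genes of the Enhancer of split and Bearded complexes, which act in Notch signalling, rose, with E(spl)m5-HLH at least 54.9-fold higher, although the list holds related copies. Endoderm and organ primordia genes rose in 7 of 8 cases, among them dan and the forkhead gene fkh (0 reads at 0–1 h against 40 and 25), and cad fell. In that list 11 rose without 0–1 h replicate 1. In this order the medians were 4.80, 5.86, 7.25, 5.84, 7.98 and 6.21, or 4.20, 5.02, 6.17, 5.67, 6.81 and 4.64 at the bounds, with unchanged counts adjusted over each list alone. Their camera adjusted p were 0.00672, 4.9e-04, 1.8e-04, 2.8e-06, 7.4e-10 and 0.00184. With an estimated correlation the adjusted p were 0.268 for the first 5 and 0.314 for the last, whose call also ended with thinning (adjusted p = 0.0543).

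Across the 26 lists 18 passed with camera and 21 with fry. With an estimated correlation camera called none, with 4 at unadjusted p under 0.05. The estimates ran from −0.109 (mesoderm) to 0.656 (ribosomal protein genes). For germ plasm and neuroblast genes they were −0.0552 and −0.0398, below the preset 0.01. Unadjusted p there still went from 7.2e-06 and 5.4e-07 to 0.0415 and 0.0337. This form of camera rests on the few residual degrees of freedom of 4 libraries, so a loss under it does not by itself show correlated genes.

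**Figure D1:**
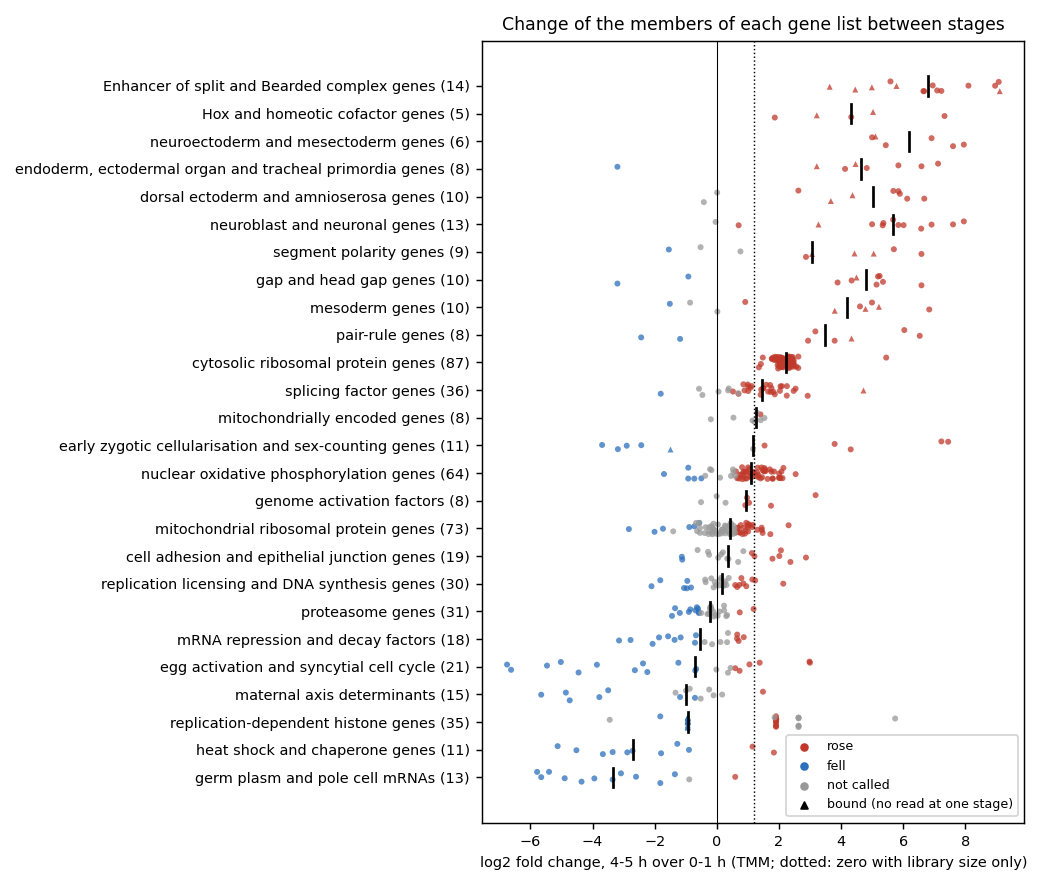
Log2 fold change, 4–5 h over 0–1 h (x axis), of each tested member of 26 gene lists (y axis, number of members in brackets). Points are genes, red where they rose, blue where they fell and grey where not called, triangles are bounds for genes with no read at 1 stage, black bars are list medians with bounds, and the dotted line is where 0 would lie with library size only: medians of the ribosomal protein (2.22), splicing and patterning lists stay to its right, while those of oxidative phosphorylation (1.10), genome activation, early zygotic, mitochondrial ribosomal protein, adhesion and replication genes lie between 0 and the line and turn negative on that scale.

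**Figure D2:**
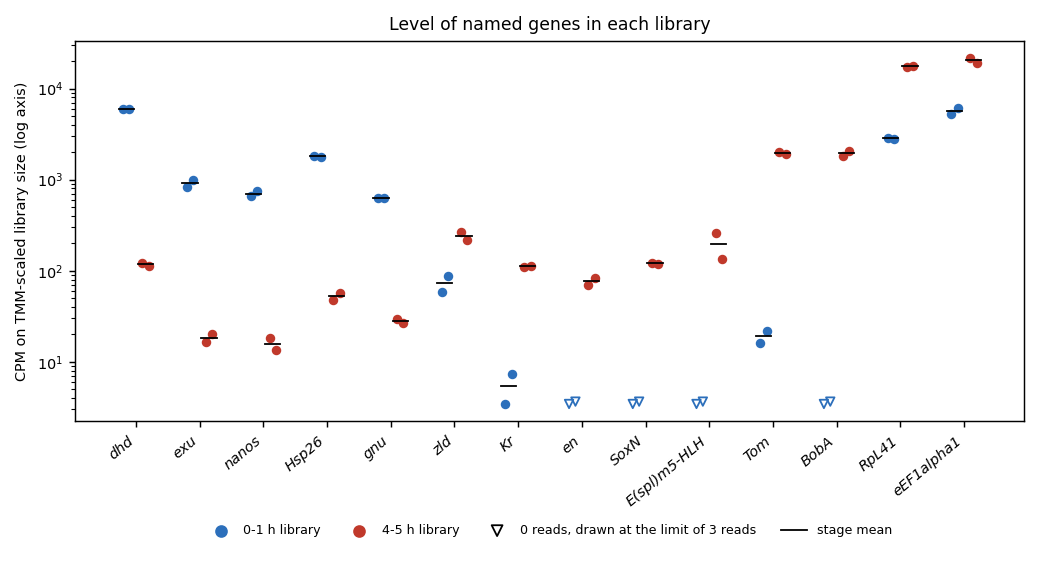
Level of 14 named genes in each library, as CPM on a log axis. Filled points are libraries (blue 0–1 h, red 4–5 h), bars are stage means, and open triangles are libraries with 0 reads drawn at the floor of 3 counts: dhd, exu, nanos, Hsp26 and gnu fell and the other 9 rose, RpL41 from 2840 to 17494 CPM, although zld and eEF1alpha1 did not rise in log2 TPM.

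Genome activation factors rose in 5 of 8 cases (also adjusted over the list alone) while nej, Clamp and Stat92E did not pass, with a median of 0.94 that becomes −0.25, with 1 higher and 3 lower, with library size only (adjusted p = 0.0483, and adjusted p = 0.314 with an estimated correlation). The pioneer factor zld rose from 73.2 ± 20.7 to 243 ± 32.7 CPM (log2 change 1.74, SE 0.26), although its change was −0.12 in log2 TPM, and tara rose 9.04-fold. The call is fragile: it was lost without 4–5 h replicate 2 (adjusted p = 0.0805), with thinning (0.106), with the stricter filter (0.109), with library size only (0.229) and with limma on TPM (0.259). Early zygotic genes divided, with 5 of 11 higher and 5 lower (the same adjusted over the list alone) and a median of 1.16, or −0.05 with library size only (adjusted p = 0.668, and adjusted p = 0.698 with an estimated correlation), although it passed with limma on TPM (adjusted p = 0.00465). Of these sala rose 174-fold, Ocho, a Bearded family gene, 149.5-fold and the sex-counting gene sisA 19.8-fold. The 5 that fell were slam (log2 change −3.19, SE 0.54), Z600 (−2.43, SE 0.52), bnk (19 and 11 reads against 0 and 1), dunk (26 and 21 against 2 and 1) and term. The whole list had 226 and 209 reads at 0–1 h, and whether the mother or the embryo made that RNA was not tested. No library covers the time between the 2 stages, so a rise and fall within it would not be seen. For the list: early zygotic cellularisation and sex-counting genes, the median relative to all genes was 0.82, 2.71, −2.39 and −0.13 without 0–1 h replicate 1, 0–1 h replicate 2, 4–5 h replicate 1 and 4–5 h replicate 2. The count filter was rerun in each of these fits, so the members tested can differ too. Its direction thus rests on the libraries and members included. Lists for other cells and stages had few tested members. Follicle cell, chorion and yolk protein genes had 0, 0, 3 and 3 reads. The 20 late muscle and cuticle genes had 119, 123, 206 and 137 reads, and only Tm1 could be tested, which rose by 1.13 (SE 0.24; −0.06 with library size only). The 18 sperm and testis genes had 89, 65, 9 and 6 reads, and only bam could be tested, which fell by 3.39 (SE 0.53). Hemocyte genes had 103, 101, 85 and 64 reads and 4 tested members, of which gcm, srp and ush rose and the scavenger receptor gene crq fell 3.25-fold.

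All 87 tested cytosolic ribosomal protein genes rose, with a median log2 change of 2.22 (camera adjusted p = 1.7e-29), and 83 of them rose with library size only, at a median of 1.03. The adjusted p was 0.308 with an estimated correlation. RpS28b rose 5.55-fold and RpL36 5.49-fold. Splicing factor genes rose in 29 of 36 cases and 1, mub, fell, with a median of 1.45, or 0.26 and 12 higher against 7 lower with library size only (adjusted p = 1.7e-07, and adjusted p = 0.268 with an estimated correlation). Hrb98DE, an hnRNP gene, rose from 167 ± 0.467 to 972 ± 137 CPM, Rsf1, an SR protein antagonist, rose 7.58-fold, and ps, a splicing regulator, was at least 26.2-fold higher. Nuclear oxidative phosphorylation genes rose in 51 of 64 cases (54 adjusted over the list alone) and 5 fell, with a median of 1.10 that becomes −0.10, with 13 higher and 14 lower, on library size only (adjusted p = 8.2e-10, adjusted p = 0.275 with an estimated correlation and 0.375 with limma on TPM). DESeq2 called 47 higher and 3 lower. ND-MLRQ rose 5.79-fold and COX8 4.33-fold, while SdhA, of complex II, fell by 1.70 (SE 0.34).

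Mitochondrial ribosomal protein genes rose in 24 of 73 cases and fell in 6 (21 and 4 adjusted over the list alone), with a median of 0.42, or −0.79 with 1 higher and 49 lower with library size only (adjusted p = 0.0483, and adjusted p = 0.482 with an estimated correlation). The call was lost without 0–1 h replicate 1 (adjusted p = 0.102) or 4–5 h replicate 1 (adjusted p = 0.0605), with thinning (0.0568), by fry (0.0979) and with no filter (0.303), and its direction turned with library size only (0.527) and limma on TPM (0.0514). DESeq2 called 15 higher and 3 lower. Without 0–1 h replicate 1 or 2 edgeR called 13 and 15 higher, and without 0–1 h replicate 2 it called 3 lower. In that list mRpL51 rose 4.95-fold and mRpL3 fell 7.12-fold. Of 8 genes encoded in the mitochondrial genome 1, mt:CoI, rose (log2 change 1.40, SE 0.22; 0.23 with library size only and −0.54 in log2 TPM), with the same count adjusted over the list alone. The list's median of 1.26, or 0.11 with library size only, did not pass (adjusted p = 0.113, and adjusted p = 0.551 with an estimated correlation), but it passed without 0–1 h replicate 2 (adjusted p = 0.0399) or 4–5 h replicate 1 (adjusted p = 0.0429), where 3 and 5 rose. Proteasome genes had 2 of 31 members higher and 10 lower (9 adjusted over the list alone), with a median of −0.21 (adjusted p = 0.175, and adjusted p = 0.551 with an estimated correlation). DESeq2 called 2 higher and 3 lower. Without 0–1 h replicate 2 edgeR called 3 lower, and without 0–1 h replicate 1 it called 1 higher. With library size only 29 of 31 fell, at a median of −1.41, and the list passed (adjusted p = 0.00132), as it did with no filter (0.0135) and limma on TPM (0.00264). The lid subunit gene Rpn5 fell 2.54-fold and Rpn2 2.72-fold. Replication genes rose in 9 of 30 cases (8 adjusted over the list alone) and fell in 6, with a median of 0.17, or −1.02 with 1 higher and 23 lower with library size only (adjusted p = 0.475, adjusted p = 0.551 with an estimated correlation and 0.0126 by fry). DESeq2 called 5 higher and 3 lower. Without 0–1 h replicate 1 or 2 edgeR called 3 and 4 higher, and without 0–1 h replicate 1 or 4–5 h replicate 1 it called 3 lower. The helicase subunit gene Mcm7 rose 4.39-fold and PolD1, of DNA polymerase delta, fell 4.30-fold. Adhesion and junction genes rose in 7 of 19 cases and fell in 2 (also adjusted over the list alone), with a median of 0.37, or −0.81 with 3 higher and 9 lower with library size only (adjusted p = 0.0816, adjusted p = 0.308 with an estimated correlation and 0.0126 by fry). DESeq2 called the same number higher and neither of the 2 lower, and the zonula occludens gene pyd rose 4.03-fold.

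Histone genes are near-identical copies among which reads are divided, so single copies are uncertain: 9 of 35 tested rose and 17 fell, also adjusted over the list alone, with a median of −1.82, or −0.94 at the bounds (adjusted p = 0.127, and adjusted p = 0.698 with an estimated correlation). Of the tested copies, 16 are His2B copies with 12 and 13 reads each at 0–1 h and none at 4–5 h. Counts of copies thus overstate separate changes. Reads summed over the 111 annotated copies came to 4608 ± 288 CPM at 0–1 h and 5239 ± 804 at 4–5 h. How far capture by poly(A) tail sets these values was not tested. The list's median relative to all genes was 2.50, 2.73 and 2.17 without 0–1 h replicate 1, 0–1 h replicate 2 and 4–5 h replicate 2 (adjusted p = 0.0184, 0.0105 and 0.224), and −6.16 without 4–5 h replicate 1 (adjusted p = 0.028). Only 1 copy fell when either 0–1 h replicate was left out, and 23 rose without 4–5 h replicate 2. Since the count filter was rerun in each fit, the copies tested can differ between them. The list passed upward with the stricter filter (adjusted p = 0.0115) and downward by fry (adjusted p = 0.0270). Pseudogenes of ribosomal RNA were among the most abundant names, and the 28SrRNA-Psi:CR40596 and 18SrRNA-Psi:CR41602 copies were not called by edgeR, at 17448 ± 12896 and 16478 ± 12359 CPM at 4–5 h. Without 4–5 h replicate 2, 28SrRNA-Psi:CR40596 passed (adjusted p = 4.8e-04), as it did with DESeq2 (0.0436) and with the robust option off (3.0e-04), where 18SrRNA-Psi:CR41602 passed too (8.1e-04).

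Some transcripts were seen at 1 stage only: 79 genes had at least 10 reads in each 0–1 h library and none at 4–5 h, and 56 had the reverse. Of the 79, 16 are near-identical His2B copies with 12 and 13 reads each, which are uncertain as separate genes, and 63 remain without them. Lost genes included krimp, of the piRNA pathway, with 90 and 84 reads (at least 13.3-fold lower), fs(1)N, of the vitelline membrane, with 97 and 63 (at least 12.1-fold lower), and shu, of the same pathway as krimp (at least 8.76-fold lower). The largest, olf186-M, had 85 and 111 reads and was at least 15.0-fold lower, and CG15093, CG8778, Men-b, which is a malic enzyme, CG9926, CG9265 and Bx, a LIM-only protein gene, were at least 8.62- to 10.8-fold lower. Gained genes included Scgdelta, a sarcoglycan of the membrane, with 423 and 351 reads (at least 273.8-fold higher), edl, an inhibitor of the Ets factor Pointed (at least 51.3-fold), ImpL2, an insulin-binding protein (at least 46.7-fold), Act87E, an actin (at least 37.1-fold), and comm, which controls axon crossing at the midline (at least 32.8-fold). Oscillin (at least 34.3-fold) and E(spl)m2-BFM (at least 31.7-fold) complete the largest rises. Actin genes are close paralogs, so the value of Act87E is uncertain. The counts rest on each library: without 4–5 h replicate 1 or 2 the genes seen at 0–1 h only were 224 and 139, and the genes seen at 4–5 h only were 101, 87 and 126 without 0–1 h replicate 1, 0–1 h replicate 2 and 4–5 h replicate 2.

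As the study is on introns, changes were compared by gene structure. Short genes, with a span under 2000 bp, were higher at 4–5 h relative to other genes: of 2227 tested 860 rose and 499 fell, with a median log2 change of 0.34 (camera adjusted p = 2.1e-04, and adjusted p = 0.491 with an estimated correlation). For short genes the call was lost by fry (adjusted p = 0.0975, as for intronless genes) and with limma on log2(TPM + 1), at a median relative to all genes of 0.18. Without ribosomal protein genes the median log2 change was 0.28. Genes spanning up to 1 kb had a median of 0.85 and rose in 53.0% of cases, those of 1 to 2 kb had 0.15, those of 2 to 5 kb −0.31, those of 5 to 10 kb −0.51, those of 10 to 20 kb −0.36 and longer ones −0.33. Of 536 intronless genes, which include Tom, BobA, SoxN and dhd, 188 rose and 137 fell, with a median of 0.31 that did not pass (adjusted p = 0.0694, and adjusted p = 0.491 with an estimated correlation). The camera adjusted p ranged from 0.0127 without 0–1 h replicate 2 to 0.276 without 4–5 h replicate 1, and was 0.0452 without 0–1 h replicate 1 and 0.0248 without 4–5 h replicate 2. Intronless genes made up 25% of those seen at 4–5 h only and 27.8% of those seen at 0–1 h only, against 8.87% of tested genes, but the 0–1 h value is 9.52% (6 of 63) without 16 His2B copies. Related Enhancer of split and Bearded genes, such as BobA, were kept in the 4–5 h value. Short genes were 23.2% of those seen at 4–5 h only, against 36.9% of tested genes, which runs against their rise. They were 41.8% of those seen at 0–1 h only, with the His2B copies included.

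Transcript forms also changed, towards forms ending further downstream at 4–5 h. In Rho1, a small GTPase of the cytoskeleton (chromosome 2R 16102687–16107229), the form Rho1-RB rose from 22.7 ± 1.68% to 96.8 ± 2.75% of the gene's reads, and Rho1-RA, which ends 740 nt upstream, went from 76.5 ± 0.627% to 0, which allows up to 1.69%. Rad23-RC, of a DNA repair gene on chromosome 4, rose from 33.4 ± 11.4% to 100% in place of a form ending upstream (at most 2.38% in a 4–5 h library). In AGO1, the microRNA effector gene, AGO1-RB held 89.0 ± 3.31% at 0–1 h, and all reads at 4–5 h were on AGO1-RD, which ends further downstream (40 and 27 reads, allowing up to 11.1% for AGO1-RB). In shep, an RNA-binding protein gene, shep-RH with the long 3′ end rose from 2.75 ± 1.67% to 96.0 ± 5.70%, at only 17 and 15 reads at 4–5 h. ND-20-RC, of a complex I subunit gene, rose from 23.6 ± 10.3% to 83.4 ± 1.91%. Other genes went otherwise. AnxB9-RF, of an annexin gene, went from 0 to 84.6 ± 7.25% at the same 3′ end as AnxB9-RC, which went from 53.0 ± 4.65% to 0. The form e(r)-RD ends upstream of e(r)-RB and rose from 16.2 ± 5.07% to 49.7 ± 13.1%. In sqd, an hnRNP gene, sqd-RE rose from 12.4 ± 0.670% to 31.7 ± 0.0328%, while the mean 3′ end of the gene moved upstream (shift −223 nt). Each of these 8 genes passed, with adjusted p from 0.0158 (sqd) to 0.0165. The limits given for forms at 0 cover counting error only, not errors in assigning reads among forms.

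Usage changed in 120 of 823 genes by the gene-level F test of edgeR (204 at unadjusted p under 0.05), and in 94 of the 120 the mean annotated length grew (78.3%, exact binomial interval 69.9–85.3%, p = 3.1e-10). It grew in 59.0% of uncalled genes (362 against 252) and in 62.1% of all tested genes, with a median log2 length ratio of 0.00867. In 77 the gained form ended further downstream, in 5 upstream and in 38 within 50 nt. With transcripts of like 3′ end summed, usage changed in 148 of 457 genes (194 unadjusted), and the mean end lay downstream at 4–5 h in 139 and upstream in 9 (93.9%, interval 88.8–97.2%, exact binomial p = 4.4e-31), with a median shift of 413 nt. These shifts are distances along the chromosome, which can include introns, and not lengths of RNA gained or lost. The largest shifts downstream were in Fs(2)Ket (6572 nt) and klar (6123 nt). Other examples, chosen after their values were seen, were brat, a translational repressor, at 5144 nt and wdb, a phosphatase subunit gene, at 3066 nt. Further ones were fs(1)h, a bromodomain gene, at 1416 nt, and in the upstream direction lola, at −6533 nt. The 309 uncalled genes had 244 shifts downstream and 58 upstream. Replicates shifted as well, over all tested genes with a value, shifts of 0 included. The median was 31.6 nt between the 0–1 h replicates (331 downstream, 112 upstream). It was −35.6 nt between the 4–5 h replicates (87 and 291, with 76 at 0), against 112 nt between stages. Among called genes with a shift, 66.2% lay downstream between 0–1 h replicates and 33.3% between 4–5 h replicates, replicate 1 against 2. The binomial test also passed between replicates of either stage, over all tested and over called genes. Its p over genes thus does not measure the spread between libraries. Each 4–5 h library lay downstream of each 0–1 h library in 62.5% to 88.5% of genes with a shift other than 0, with medians of 49.2 to 176 nt over all, so the size of the stage shift depends on the libraries compared. Of the preset isoform genes Sxl, CycB, Kr, lola, mod(mdg4), pbl, E2f1 and brat could be tested on single transcripts, and none passed (smallest adjusted p = 0.116, E2f1), while brat and lola passed on summed ends. The calls are fragile: by the Simes adjustment in edgeR no gene passed on transcripts (118 at unadjusted p under 0.05) and 77 on summed ends. A replicate block left 0 genes on either feature, and the stricter filter left 0 on transcripts and 90 on summed ends. Leaving out 0–1 h replicate 1, 0–1 h replicate 2, 4–5 h replicate 1 or 4–5 h replicate 2 left 0, 0, 1 and 0 genes on either feature (358, 227, 383 and 236 unadjusted on transcripts, 266, 173, 253 and 174 on ends). In the same order the 3' end shift of all tested genes, percent downstream, was 87.2, 76.1, 85.0 and 70.1, against 85.1 with all libraries. Replicates also differ: of 457 genes with at least 50 reads per library, the major isoform differed between replicates in 72 at 0–1 h and in 117 at 4–5 h.

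**Figure D3:**
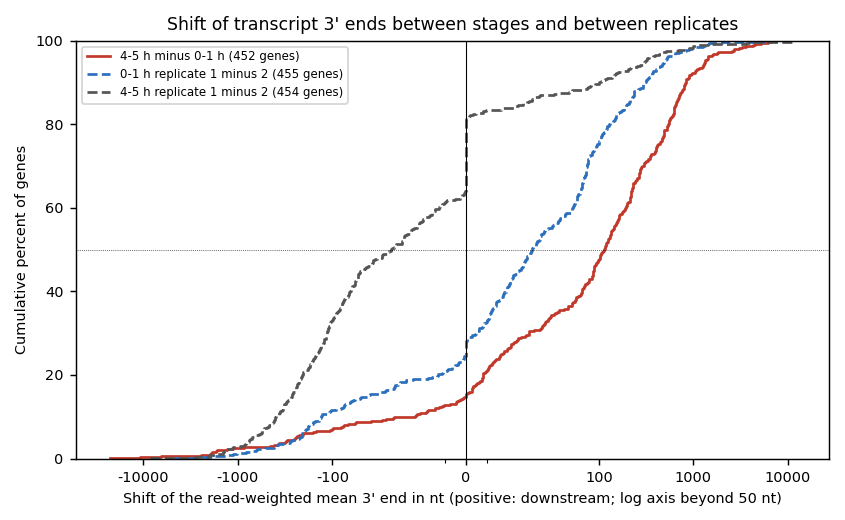
Cumulative percent of genes (y axis) by the shift of the read-weighted mean 3′ end in nt (x axis, log beyond 50 nt, positive downstream), for all tested genes with a value, between stages (red) and between the replicates of each stage (dashed). Shifts are distances along the chromosome and can include introns. The median is 112 nt between stages, 31.6 nt between 0–1 h replicates and −35.6 nt between 4–5 h replicates, or 114, 33.7 and −58.8 nt among genes with a shift other than 0, so libraries of the same stage differ too.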

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

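Genes called depend on the tool and on scaling, and usage calls depend on the number of libraries and on the model. Alternatives fixed in advance gave genes changed between stages of 2424 (DESeq2) to 5110 (limma on log2(TPM + 1)), and leaving out each library gave 2819 to 3431. Alternatives added after seeing the data were a block with crossed replicate numbers, a bias-adjusted quasi-likelihood fit, leaving out ribosomal protein genes or unmatched transcripts, leaving out histone copies among genes seen at 1 stage, leaving Tl out of the pair-rule list, comparing single libraries across stages, and every result on summed 3′ ends. The fits among these gave 3549 to 3788 genes. The cause of a difference was not tested unless given.

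The genes higher at 4-5 h were 656 with library size only and 312 with limma on log2(TPM + 1), and genes lower at 4-5 h were 3823 and 4798, and 1124 with DESeq2. The number of genes changed at least 4-fold was 2208 with library size only and 2778 with limma. Of genes at least 4-fold higher at 4-5 h there were 223 with library size only, 152 with limma and 975 with no filter, which tests more genes, and of genes at least 4-fold lower at 4-5 h 1985 and 2626. Gene lists that passed were 11 thinned to the smallest library, which has fewer reads, 0 with camera with estimated correlation, and 17 to 20 without each library.

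For list: mitochondrial ribosomal protein genes, camera's direction turned with library size only (median relative to all genes 0.50, adjusted p = 0.527) and with limma on log2(TPM + 1) (0.16). For list: replication-dependent histone genes it turned with library size only (−1.72), no filter (1.88), stricter filter (2.75) and thinned to the smallest library (1.98), and without each library the range was −6.16 to 2.73. For list: replication licensing and DNA synthesis genes it turned with library size only (0.27), no filter (−0.16) and limma (0.12). With library size only the medians of these lists hardly moved from those of the main fit, 0.51, −1.72 and 0.27 in the same order. What turned there was camera's direction, not the sign of the median. For list: early zygotic cellularisation and sex-counting genes, the range without each library was −2.39 to 2.71.

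For intronless genes the median relative to all genes and the camera adjusted p were 0.41 and 0.0218 with library size only, 0.53 and 0.0134 with the stricter filter, 0.41 and 0.0295 with the replicate block, and 0.41 and 0.0311 thinned, so that the list passed in these. The median was 0.20 with limma on log2(TPM + 1), where it passed only before adjustment, and 0.19 to 0.51 without each library. For short genes limma on log2(TPM + 1) gave 0.18, where the list no longer passed.

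Log2 changes of these genes turned with library size only: gene: Bap60 −0.23, gene: Tm1 −0.0616, gene: mt:CoIII −0.000282, gene: Rpt4 −0.00629, gene: sqd −0.17, gene: AnxB9 −0.28, gene: ND-20 −0.45, gene: e(r) −0.61, gene: Rad23 −0.83 and gene: AGO1 −1.09. With limma on log2(TPM + 1), where no scaling beyond TPM is applied, these turned: zld −0.12, Bap60 −0.99, Tm1 −0.75, mRpS33 −0.26, mt:CoI −0.54, mt:CoIII −0.84, mt:CoII −0.78, Rpt4 −0.75, His4:CG33903 −0.0639, His4:CG31611 −0.0690, eEF1alpha1 −0.14, RpS27A −0.0421, sqd −1.22, AnxB9 −1.15, ND-20 −1.59, Rho1 −0.83, e(r) −1.28, Rad23 −1.92 and AGO1 −1.89. The change of AGO1 was −0.0309 to 0.262 without each library, below 0 without 4-5 h replicate 2. Of 109 named genes 96 kept their direction and call with library size only and 106 with DESeq2.

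The genes detected at one stage were 229 with 5 or more reads and 179 to 292 without each library, genes detected only at 0-1 h 89 to 224, and genes detected only at 4-5 h 131 with 5 or more reads and 68 to 126. Fewer libraries make it easier to have no read at a stage.

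Isoform usage changed in 0 genes with the Simes adjustment and 0 with the stricter filter (153 at unadjusted p under 0.05), in 237 with the bias-adjusted quasi-likelihood fit, and in 0 to 1 without each library, where fewer residual degrees of freedom remain. For 3′ end usage changed the values were 77 with the Simes adjustment, 90 with the stricter filter, 347 with the bias-adjusted fit and 0 to 1 without each library.

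The replicate numbers are no known batch, and the deviations of same-numbered libraries correlated at −0.159 across genes. This does not exclude that the numbers pair the libraries. The rRNA share was higher in replicate 1 at both stages (2.20% against 0.736%, 5.33% against 3.21%). The mitochondrial share was higher in replicate 2 at both (0.430% against 0.285%, 0.537% against 0.237%). The ribosomal protein share did not follow the numbers (23.3% and 26.2%, then 50.2% and 49.8%). A replicate block gave 3262 genes changed between stages, 0 genes with isoform usage changed (91 unadjusted) and 0 with 3′ end usage changed (144 unadjusted, edgeR). Under the block the egg activation list passed (adjusted p = 0.00994), the genome activation and mitochondrial ribosomal protein lists did not (0.127 and 0.185), and 28SrRNA-Psi:CR40596 and 18SrRNA-Psi:CR41602 passed (1.2e-09 and 7.7e-18). With crossed numbers the block gave 3788, 0 (184 unadjusted) and 79 (193 unadjusted).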

Other observations

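Gene families defined by symbol after the data were seen divide the protein-making machinery. Translation initiation factors rose in 22 of 35 cases and fell in 3, with a median log2 change of 0.84 that becomes −0.35 with library size only (camera adjusted p = 2.8e-04, and adjusted p = 0.347 with an estimated correlation). All 6 elongation factors rose, with a median of 1.85, or 0.67 with library size only (adjusted p = 6.9e-04, and adjusted p = 0.359 with an estimated correlation). The helicase gene eIF4A rose by 2.00 (SE 0.21) and eEF5 by 2.37 (SE 0.20). Aminoacyl-tRNA synthetases, which charge tRNAs, went the other way: 19 of 29 fell and 1, TyrRS, rose, with a median of −1.18 (adjusted p = 2.8e-04, and adjusted p = 0.282 with an estimated correlation), and MetRS fell by 2.62 (SE 0.40). All 8 subunits of the CCT chaperonin, which folds actin and tubulin, fell, with a median of −2.02 (adjusted p = 2.8e-04, and adjusted p = 0.359 with an estimated correlation), and CCT2 fell by 2.99 (SE 0.24). Of 16 subunits of the V-type proton pump 10 fell, with a median of −1.27 (adjusted p = 0.00139, and adjusted p = 0.282 with an estimated correlation), and Vha68-2 fell by 4.07 (SE 0.32).

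Tubulins, chosen in the same way, divided, although related sequences make single members uncertain. The egg form alphaTub67C fell from 651 ± 89.7 to 10.3 ± 4.23 CPM, and gammaTub37C went from 76 and 83 reads to 0 and 1. By contrast alphaTub84B, already at 738 ± 54.6 CPM at 0–1 h, rose by 3.27 (SE 0.21), betaTub56D by 2.90 (SE 0.21) and gammaTub23C by 1.47 (SE 0.36), so that 5 of 7 rose and 2 fell, with a median of 2.49 that did not pass with camera (adjusted p = 0.143, adjusted p = 0.492 with an estimated correlation and 0.0493 by fry). Cyclins rose in 6 of 12 cases and fell in 3, with a median of 0.53, a mean of −0.17 and −0.66 as the median with library size only (adjusted p = 0.291, and adjusted p = 0.492 with an estimated correlation). Ubiquitin-conjugating enzymes rose in 2 of 7 cases and fell in 1, with a median of 0.51, or −0.69 with library size only (adjusted p = 0.291, and adjusted p = 0.492 with an estimated correlation). Genes of chromosome X rose in 250 cases of 1067 and fell in 409, with a median of −0.39 (camera adjusted p = 0.249, 0.322 with an estimated correlation and 0.00818 by fry). With no filter, which adds genes to compare with, camera passed (adjusted p = 0.00314, and 0.0477 with an estimated correlation). By fry the X passed with TMM, RLE and DESeq2 scaling. It also passed with library size only, where the median of all genes was −1.29. Passing by fry there does not set the X apart, and camera gave adjusted p = 0.374. The call by fry was lost without 0–1 h replicate 1, 0–1 h replicate 2 or 4–5 h replicate 1, at medians of −0.37, −0.44 and −0.43. Chromosome 4 went the other way, with 18 of 45 genes higher and 9 lower and a median of 0.50, or −0.71 with 5 higher and 19 lower with library size only, and did not pass (adjusted p = 0.168, and adjusted p = 0.0852 by fry).

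For ribosomal protein genes, the test of TMM scaling was chosen after the result was seen. If the scaling alone made the rise, it should vanish with library size only, but the median was then 1.03 and 83 of 87 genes rose. If direct RNA libraries at 4–5 h took up short transcripts better, genes of like transcript length should rise as much, but 334 matched genes had a median of 0.77, 1.44 below that of the ribosomal protein genes. Capture by length may still add to the rise, since 51.8% of those matched genes rose as well. A stage-wide difference in library preparation, or longer poly(A) tails that ligate better at 4–5 h, is confounded with stage and stays open, beside the hypothesis that these mRNAs make up more of the embryo's messages.

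For 3′ ends further downstream, the comparison itself and all tests given here were chosen after the result was seen. Errors in assigning reads among forms that end within 50 nt are argued against, since with such forms summed 93.9% of the 148 changed genes still shifted downstream. Summing does not address errors in assigning reads among forms whose ends lie further apart, so these stay open. Differences in 3′ end capture from library to library remain a candidate explanation: over all tested genes with a value the larger median shift between replicates was −35.6 nt (4–5 h), or 31.7% of the 112 nt between stages (−58.8 nt or 51.6% among genes with a shift other than 0), which neither shows nor excludes this. Loss of the upstream-ended forms alone also stays open: in genes chosen in 1 pair of libraries and measured in the other, the downstream form was higher in 72.8% to 85.0% of genes with TMM and in 48.5% to 69.1% with library size only, at least 25.2 percentage points above the share of all tested genes, but a form unchanged per embryo would also rise relative to a falling bulk. Greater use of downstream ends by zygotic transcription is therefore a hypothesis that these libraries do not separate from capture or from read assignment. Stage-wide effects of tails or library preparation are untested.

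For short genes, both tests were written before their results. Capture by transcript length differed between the 4–5 h replicates (slope of the log2 ratio on log2 length −0.174), against −0.293 between stages and 0.119 between the 0–1 h replicates, so part of the stage slope could come from library differences. With transcript length in the model, the term for short genes went from 0.54 to 0.0978 (95% interval −0.0694 to 0.265). Transcript length in place of gene span is thus a candidate explanation, and a separate effect of gene span was not resolved. What sets the dependence on transcript length, biology or capture, stays open.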
